A study of Mus musculus with 24 samples.

How the data were processed

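The deposited table holds whole read counts per gene for 24 libraries and 47643 genes. Per the submitters' processing notes, reads from SMART-seq v2 libraries were aligned to mm10 (GRCm38) with STAR and counted over GENCODE vM9 genes. Per the file header, featureCounts 1.5.0-p1 made the counts from read pairs without a strand setting and without reads that map to several places or to several genes. Antisense reads were therefore counted with the gene they overlap. The protocol names a spike-in of ERCC RNA, and the table holds 0 ERCC rows.

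Samples were put into 8 groups of 3 from the labels alone. Gene IDs were matched to symbols in the supplied annotation, which gave a symbol to 47224 IDs and none to 419, with 0.063% of the counts. Another 120 rows share a symbol with another row and were kept as separate genes. Replicate libraries were compared by correlation and by a chi-square test, and no 2 libraries held the same counts.

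Differences were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr over the 8 groups (minimum count 10, minimum total 15), which left 15000. Libraries were scaled by the TMM method. All 24 libraries entered 1 quasi-likelihood fit with robust dispersion and 1 coefficient per group, and 15 contrasts were drawn from it. The biological coefficient of variation was 0.338 and the median prior degrees of freedom 8.26. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and genes below 0.05 were called. Interactions are the day 0 to later change in iPSC-derived cells minus that in bone marrow-derived cells.

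Gene groups were 43 gene lists fixed before the data were examined, 3 of whose symbols were not in the annotation. For each list the members called over all genes were counted, and again with p-values adjusted over the list alone. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01 and with an estimated correlation, adjusted by the Benjamini-Hochberg method.

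Genes named in the text follow a fixed rule. It takes the largest called changes in each direction with no overlap between replicates and a mean of at least 20 CPM in the higher group. It takes 10 per direction for the 2 day 12 changes and for the source differences at days 0 and 12, and 4 per direction elsewhere. It adds 30 fixed genes, 29 of which were tested, and the list members with the lowest adjusted p or with a change against their list. Predicted genes named only by a number or by a clone were left out.

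Where a group had 0 counts for a gene, the change is given as at least the fold that a floor of 3 counts over its 3 libraries allows. With 1 to 3 counts it is a ratio of library-scaled counts with an exact 95% interval for counting error. In a simulation on the iPSC-derived day 12 contrast over 15000 genes, 56% of genes changed 2-fold and 87% of those changed 4-fold were recovered, and 3.4% of calls were false. It changed 100 genes at each fold, none of them from the least expressed, and gave both sources the same dispersion for a gene. Recovery therefore does not cover genes near 0 counts. Neither value covers the larger replicate spread of iPSC-derived libraries. Principal components used log2 CPM with a prior count of 2. Alternative settings included DESeq2 1.42.0. Tables were read with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9.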

Results

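The data are RNA-seq read counts per gene from 24 libraries of mouse macrophages. Macrophages derived from induced pluripotent stem cells (iPSC-derived) and from bone marrow (bone marrow-derived) were each sampled at day 0 without co-culture and after 3, 6 and 12 days of co-culture. That gives 8 groups with n = 3 independent replicates each, per the series' design text. The labels do not name the co-culture partner. Library totals ran from 5839316 to 11805478 counts, and 15357 to 18321 genes had at least 1 count in a library. Levels are given as CPM (counts scaled to library size) with the standard deviation (SD) over 3 libraries. Changes are given as log2 fold changes with a standard error (SE) from edgeR, adjusted by the Benjamini-Hochberg method over 15000 tested genes. "Rose", "fell" and "changed" are used only where the adjusted p was below 0.05. The p-values rest on the spread between replicates, pooled over all 24 libraries, and cover nothing else. Intervals and "at least" folds for genes with 3 or fewer counts in a group cover counting error only.

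On the first 2 principal components the sources lay apart and day 0 lay apart from co-culture within each source, while iPSC-derived day 6 and day 12 lay close together. The first principal component held 25.4% of the variance and the second 17.8%. Correlations between libraries of the same group ran from 0.921 to 0.969. Day 0 and co-cultured samples differ in both time and co-culture, so a change from day 0 covers both.

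**Figure D1:**
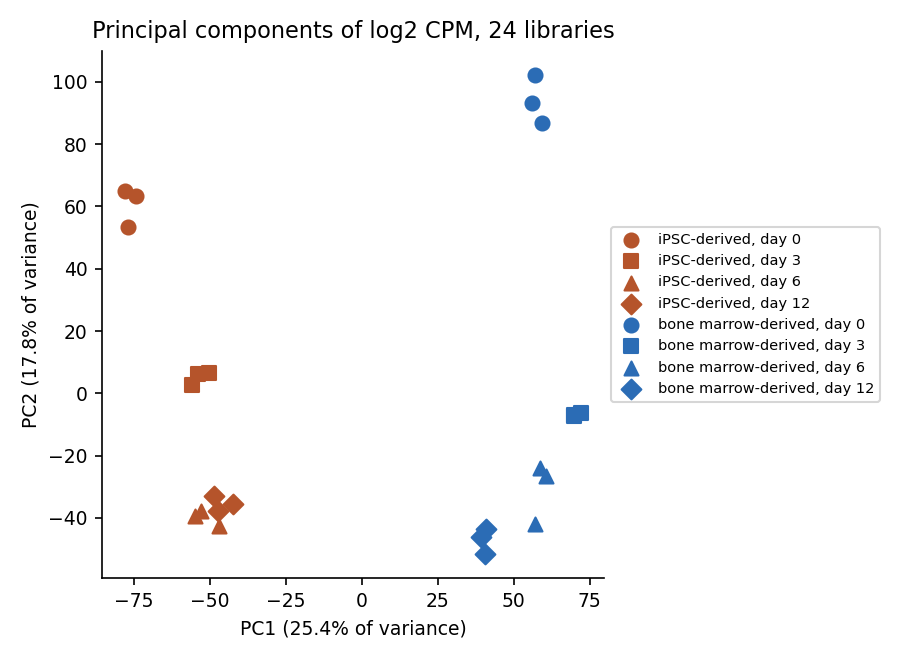
Principal components of log2 CPM for all 24 libraries. Colour gives the macrophage source and marker shape gives the day.

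The first question is which genes differed after 12 days of co-culture in iPSC-derived macrophages (n = 3 against n = 3). The microglial genes P2ry12, Tmem119, Cx3cr1 and Fcrls all rose. P2ry12, a purinergic receptor of microglial processes, went from 22.7 ± 5.11 to 88.7 ± 31.9 CPM (SD, n = 3; log2 fold change 1.97 ± 0.27 SE, adjusted p = 5.3e-06). Tmem119, a membrane protein used as a microglial marker, went from 1.66 ± 1.72 to 98.4 ± 36.1 CPM (5.88 ± 0.50, adjusted p = 2.0e-08). Its 3 day 0 libraries held 1.53, 0 and 3.43 CPM, so the size of this fold depends on the library. The fractalkine receptor gene Cx3cr1 rose by 3.32 ± 0.40 log2 units to 910 ± 156 CPM. Fcrls, an Fc receptor-like scavenger gene of microglia, rose by 5.08 ± 0.30 to 3581 ± 1060 CPM. In GRCm38/mm10 coordinates P2ry12 (ENSMUSG00000036353.13) is on chromosome 3 at 59216272 to 59262871. Tmem119 (ENSMUSG00000054675.5) is on chromosome 5 at 113793729 to 113800516, and Cx3cr1 (ENSMUSG00000052336.6) on chromosome 9 at 119901616 to 120068283.

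Other genes of tissue macrophages rose in the same comparison. Apoe, which encodes a lipid carrier, rose by 3.82 ± 0.20 log2 units (adjusted p = 7.0e-12). C1qa, a complement subunit gene, rose by 3.29 ± 0.20 to 2952 ± 186 CPM. Olfml3 (3.92 ± 0.35), Csf1r (1.06 ± 0.18) and Mrc1 (1.82 ± 0.33) rose as well. Sall1, a transcription factor gene of microglia, had no counts at day 0 and was at least 28.1-fold higher. Gpr34 (adjusted p = 0.06), Slc2a5, Trem2, Ptprc, Ccr2 and Mki67 did not pass, and Siglech had no counts in either group.

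Acod1, Il7r and Trib3 were among the largest falls. Acod1, which encodes the enzyme that makes itaconate, fell from 1148 ± 293 to 4.92 ± 3.36 CPM (log2 fold change -7.85 ± 0.62 SE, adjusted p = 2.4e-08). The cytokine receptor gene Il7r fell from 119 ± 53.9 to 0.421 ± 0.361 CPM (-8.10 ± 0.56), and the stress-response pseudokinase gene Trib3 from 188 ± 69.9 to 2.70 ± 2.41 CPM (-6.09 ± 0.64). Aqp9 (-7.96 ± 1.21), Atp8b4 (-6.20 ± 0.66), Cadps (-5.74 ± 1.39), Oit3 (-5.30 ± 0.45) and Ptgir (-5.26 ± 0.58) were also among the 10 largest falls, and Gpr141 and Car6 were at least 215-fold and 204-fold lower. Of the largest rises, Slco4a1, an organic anion transporter gene, went up by 8.89 ± 1.19 log2 units to 556 ± 600 CPM, and by 7.64 without day 12 replicate 2. Nr4a1, an immediate early nuclear receptor gene, rose by 6.52 ± 0.73, the growth factor gene Pdgfc by 7.54 ± 0.85 and the cytokine gene Il1b by 5.98 ± 1.14. Il1b was 27.4, 170 and 4.35 CPM in the 3 day 12 libraries, and its rise was 3.90 without replicate 2 and 8.57 without day 0 replicate 1. Nxpe5 was at least 191-fold higher. Count ratios were 512 (95% interval 141 to 4230) for Bmp2, 608 (109 to 24100) for Pmepa1 and 216 (73.7 to 1050) for Olig1, which stood at 22.3 ± 22.9 CPM. Tnf fell by 1.20 ± 0.30 and Cd74 by 2.20 ± 0.44 log2 units.

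Among gene groups at day 12 in iPSC-derived macrophages, 17 of 25 microglia signature genes rose and 1 fell (20 and 1 when adjusted over the list alone), with a median log2 fold change of 2.72. Selplg fell (-0.57), and Slco2b1 rose by 3.23 ± 0.26. Of 21 general macrophage genes 16 rose and 0 fell, among them Mertk (1.62) and Irf8 (1.25). TGF-beta response genes rose 13 of 21 with 1 fall (14 and 2 adjusted over the list alone), for example Tgfbr2 (1.92), Tgfbr1 (1.39) and Id3 (4.23), with Bambi falling (-0.81). Of 30 glycolysis and hypoxia genes 20 fell and 0 rose. The glycolytic aldolase gene Aldoa fell from 3816 ± 412 to 1164 ± 151 CPM (-1.71 ± 0.12), Pfkp by 2.89 ± 0.21 and Pgk1 by 2.21 log2 units. ATF4 and unfolded protein response genes fell 17 of 22 with 0 rises (0 and 18 adjusted over the list alone): Mthfd2, a mitochondrial folate enzyme gene, by 3.43 ± 0.25, Phgdh by 4.71 and Atf4 itself by 2.18. Of 17 NRF2 antioxidant genes 15 fell and 0 rose (0 and 16 adjusted over the list alone), including Srxn1 (-3.12) and G6pdx (-1.45). The camera test called these 6 lists with its preset correlation and with an estimated one.

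Interferon response genes fell 19 of 30 with 0 rises (0 and 20 adjusted over the list alone) in this comparison. Oasl1, an interferon-induced antiviral gene, fell by 4.76 ± 0.34 log2 units, Rsad2 by 2.87 and Usp18 by 2.27, and the camera call was lost at adjusted p = 0.09 with an estimated correlation. Inflammatory NF-kB genes were mixed, with 6 of 28 higher and 10 lower (6 and 11 adjusted over the list alone): Ccl5 (-4.88) and Nfkbia fell, Socs3 (3.41) and Nlrp3 (1.55) rose. Of 19 immediate early genes 10 rose and 0 fell (11 and 0 adjusted over the list alone), including Fos (3.16 ± 0.33), Junb (2.39) and Zfp36 (3.08). Phagocytosis genes rose 21 of 30 with 4 falls (21 and 5 adjusted over the list alone), with Itgb5 (2.35) and Fcgr2b (2.34) higher and Itgax (-3.05) and Marco (-4.67) lower. Border-associated macrophage markers rose 10 of 14 with 0 falls (12 and 0 adjusted over the list alone), including Stab1 (2.47 ± 0.24) and Folr2 (1.66). LXR target genes rose 8 of 14 with 2 falls (9 and 2 adjusted over the list alone), with Abca1 at 2.27 and Abcg1 at 4.24. Of 23 cholesterol biosynthesis genes 0 rose and 8 fell. Lysosome genes were split, 13 of 40 higher and 7 lower (13 and 8 adjusted over the list alone), and so were cell cycle genes, 3 of 35 higher and 5 lower, with Mcm4 (0.97) up and Ccnb2 (-1.57) down. Ribosomal protein genes and oxidative phosphorylation genes had 4 of 31 lower each and 0 higher.

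In total 3706 genes were called at day 12 against day 0 in iPSC-derived macrophages, 2099 higher and 1607 lower. With no scaling factors the call was 1733 higher and 2057 lower and the all-gene median moved by -0.13. A fit on only the groups compared called 2106 genes, and without genes under 1 CPM in both day 0 groups the split was 1634 and 1607.

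**Figure D2:**
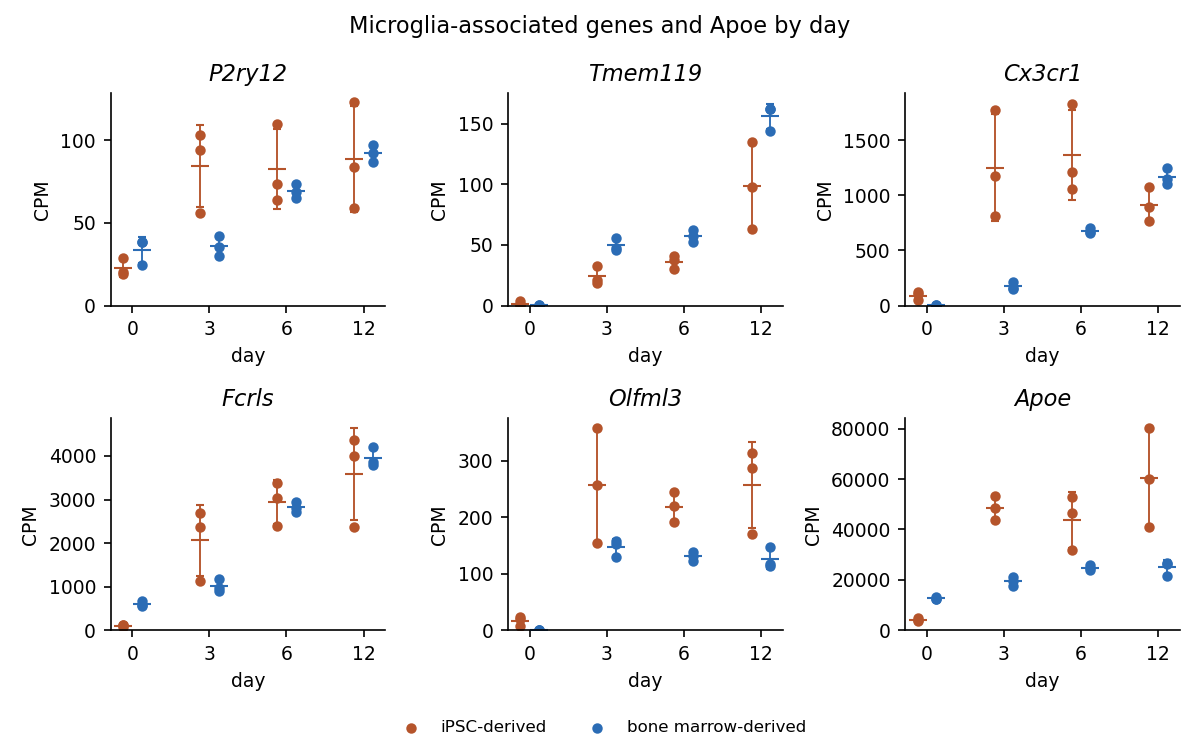
CPM of 5 microglia-associated genes and Apoe by day in both sources. Points are libraries, dashes are means and bars are SD (n = 3).

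Genes of neural and connective-tissue cells were counted in the co-cultured iPSC-derived libraries. Gfap, an astrocyte filament gene, went from 0.0365 ± 0.0632 to 43.0 ± 1.5 CPM by day 12 (count ratio 1190, 95% interval 212 to 46900). Col1a1, a fibroblast collagen gene, rose by 4.79 ± 1.00 log2 units to 113 ± 50.1 CPM from 0.766, 1.75 and 9.65 CPM in the 3 day 0 libraries, Dcn by 7.17 ± 1.05 and Col1a2 by 5.98 ± 0.87. The neuronal genes Stmn2 and Tubb3 had day 12 count ratios of 56.6 (9.77 to 2270) and 76.7 (13.4 to 3070). Fibroblast genes rose 9 of 12 with 0 falls (10 and 0 adjusted over the list alone). Astrocyte genes rose 9 of 12 with 3 falls, Slc1a3 (4.52 ± 0.62) and Atp1b2 (4.06) up and Aldh1l1 (-1.68), Clu (-1.70) and Aldoc (-1.04) down. Neuron genes rose 9 of 19 with 1 fall, Map2 up by 5.43 ± 0.91 and Uchl1 down (-2.71). Oligodendrocyte genes rose 7 of 12 with 1 fall (8 and 1 adjusted over the list alone), Mbp by 1.35 ± 0.26, with Cspg4 lower (-2.21). Mbp and Cspg4 already stood at 44.6 and 57.9 CPM at day 0, without co-culture. The imprinted gene transcripts H19 and Meg3 rose by 4.37 and 4.66.

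**Figure D3:**
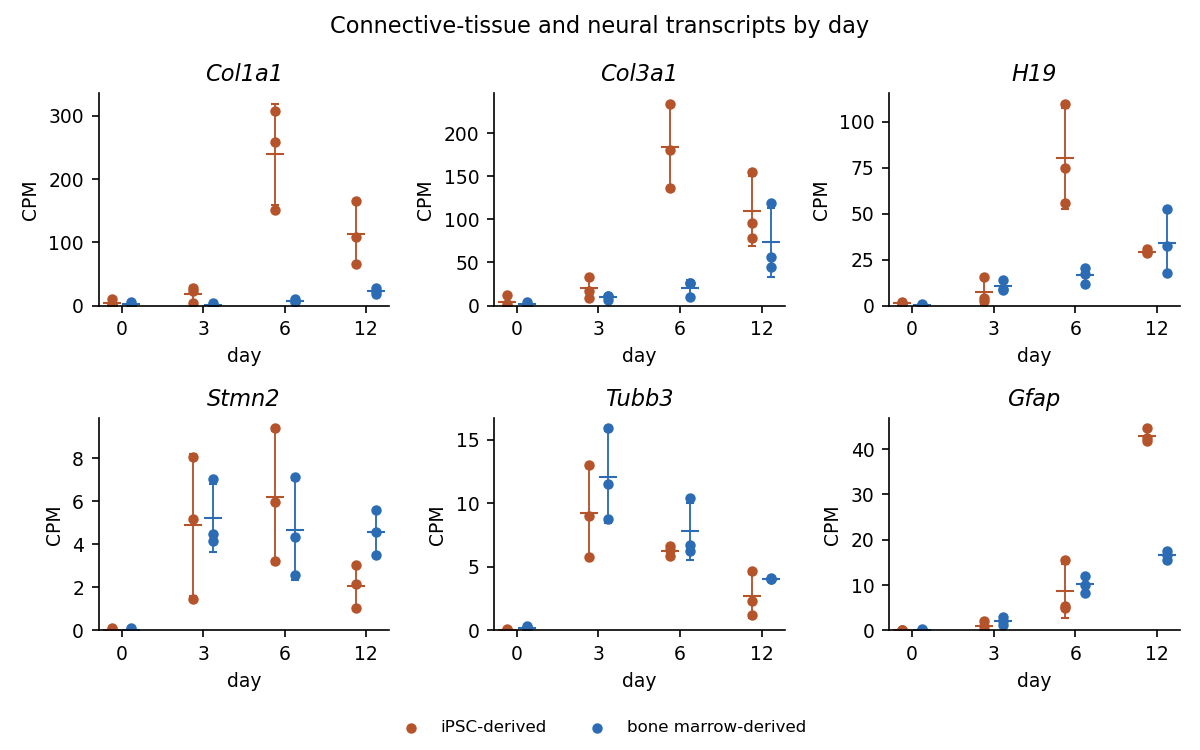
CPM of 6 connective-tissue and neural transcripts by day in both sources. Points are libraries, dashes are means and bars are SD (n = 3).

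Day 3 against day 0 asks how early the iPSC-derived cells differed (n = 3 against n = 3). Fcrls had risen by 4.28 ± 0.29 log2 units, Cx3cr1 by 3.79 ± 0.41, Tmem119 by 3.85 ± 0.48 and Olfml3, an extracellular protein gene of microglia, by 3.92 ± 0.35. P2ry12 had risen by 1.90 ± 0.27, Gpr34 by 3.04 ± 0.56, Apoe by 3.50 ± 0.20, C1qa by 1.91 and Trem2 by 0.95. Sall1 was at least 9.63-fold and Siglech, a lectin gene of microglia, at least 11-fold higher. Of the largest changes, Vnn3 was at least 216-fold higher, Bmp2 had a count ratio of 456 (95% interval 126 to 3770), and Cdo1 (6.17 ± 0.66) and Npnt (6.08 ± 1.19) rose. Aqp9 was at least 338-fold lower, and the neutrophil chemokine gene Cxcl2 (-8.30 ± 0.84), Acod1 (-7.19 ± 0.60) and the lectin receptor gene Clec4e (-6.19 ± 0.55) fell. Tnf fell by 3.34 ± 0.33 and Mki67, a proliferation marker, by 1.13.

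Microglia signature genes rose 19 of 25 with 0 falls at day 3 (21 and 0 adjusted over the list alone), and general macrophage genes 14 of 21 with 0 falls, Mertk by 2.68. Lysosome genes rose 26 of 40 with 3 falls (27 and 3 adjusted over the list alone), including the protease gene Ctsd (1.51), Man2b1 (2.09) and Psap (1.34), with Ctsk lower (-2.92). Disease-associated microglia genes rose 15 of 24 with 0 falls (16 and 1 adjusted over the list alone), Clec7a by 3.48. Phagocytosis genes rose 19 of 30 with 1 fall (22 and 1 adjusted over the list alone). LXR targets rose 7 of 14 with 1 fall (8 and 2 adjusted over the list alone), the lipid transporter gene Abca1 by 3.13 and Pltp by 3.37, with Scd1 lower (-2.34). Glycolysis and hypoxia genes fell 24 of 30 with 1 rise, Tpi1 by 2.12 and Aldoa by 1.93, and Pfkfb3 rose (0.71). ATF4 genes fell 21 of 22 with 0 rises, Mthfd2 by 4.10 and Phgdh by 4.49. Cholesterol biosynthesis genes fell 18 of 23 with 0 rises (0 and 20 adjusted over the list alone), Fdft1 by 1.58 and Sqle by 1.57. Inflammatory NF-kB genes fell 14 of 28 with 1 rise (1 and 18 adjusted over the list alone), Nfkbia by 2.48. Neuron genes rose 9 of 19 with 1 fall (12 and 1 adjusted over the list alone), and the count ratio was 252 (95% interval 44.7 to 9980) for Tubb3 and 131 (23.1 to 5210) for Stmn2. Fibroblast genes rose 3 of 12 with 0 falls.

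The total at day 3 in iPSC-derived cells was 2907 genes, 1686 higher and 1221 lower. With no scaling factors it was 1259 higher and 2082 lower with the all-gene median moved by -0.19. A fit on only the groups compared called 1849.

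Day 6 against day 0 places the iPSC-derived changes between the early and late samples (n = 3 against n = 3). Fcrls was higher by 4.80 ± 0.30 log2 units, Tmem119 by 4.43 ± 0.49, Cx3cr1 by 3.91 ± 0.42, P2ry12 by 1.86 ± 0.27 and C1qa by 2.33 ± 0.20. Acod1 fell by 8.73 ± 0.65, Tnf by 2.41 and Mki67 by 1.28. Ncan, a proteoglycan gene of neural tissue, rose by 6.65 ± 0.62. Col8a1 and Msln were at least 269-fold and 200-fold higher, and Bmp2 had a count ratio of 386 (95% interval 107 to 3200). Aqp9 was at least 332-fold lower, with count ratios of 589 (105 to 23300) for the fall of Gpr141 and 280 (77.2 to 2320) for that of Car6. Col1a1 reached 239 ± 80.2 CPM, against 18.3 ± 12.2 at day 3.

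At day 6 microglia signature genes rose 20 of 25 with 0 falls (21 and 1 adjusted over the list alone) in iPSC-derived cells. Interferon response genes fell 22 of 30 with 0 rises (0 and 23 adjusted over the list alone), Oasl1 by 4.20 ± 0.33, with the camera call lost at adjusted p = 0.071 with an estimated correlation. Cell cycle genes fell 20 of 35 with 0 rises, Aurka by 2.20, and that camera call was lost at adjusted p = 0.33 with an estimated correlation. Genes of glycolysis and hypoxia fell 19 of 30 with 0 rises (1 and 21 adjusted over the list alone), Aldoa by 2.19, and ATF4 genes 19 of 22 with 0 rises, Mthfd2 by 4.02. NRF2 genes fell 12 of 17 with 0 rises (0 and 16 adjusted over the list alone), Srxn1 by 2.77. Fibroblast genes rose 9 of 12 with 0 falls (10 and 0 adjusted over the list alone), Col1a2 by 6.38 ± 0.88 and the smooth muscle actin gene Acta2 by 5.02. Oligodendrocyte genes rose 9 of 12 with 0 falls (10 and 0 adjusted over the list alone), Mbp by 1.38. Neuron genes rose 10 of 19 with 1 fall (11 and 1 adjusted over the list alone), Map2 by 6.23, and astrocyte genes 8 of 12 with 1 fall, Slc1a3 by 4.59. The fetal and imprinted genes H19 (5.82), Meg3 (6.08) and Igf2 (5.77) rose. In all, 3804 genes changed at day 6, 2147 up and 1657 down, and a fit on only the groups compared called 1938. Without genes under 1 CPM in both day 0 groups it was 1611 up and 1647 down.

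Day 12 against day 3 asks what differed during co-culture itself in iPSC-derived cells (n = 3 against n = 3). Tmem119 rose again by 2.02 ± 0.39 log2 units and C1qa by 1.37 ± 0.19, while P2ry12 (0.07), Olfml3 (0.00), Cx3cr1 (-0.46) and Fcrls (0.80, adjusted p = 0.055) did not pass. Slco4a1 rose by 8.43 ± 1.15 (7.17 without day 12 replicate 2), Nxpe5 by 5.91 ± 0.97, the chemokine gene Ccl12 by 5.79 ± 0.68 and Ccn1, a matricellular protein gene, by 5.65 ± 0.57. Il7r (-6.45 ± 0.55), the scavenger receptor gene Marco (-5.86 ± 0.86), the integrin gene Itgax (-4.31 ± 0.40) and Adgre5 (-3.17 ± 0.36) fell. Immediate early genes rose 15 of 19 with 0 falls (19 and 0 adjusted over the list alone), Fosb by 5.58, Fos by 2.83 and Jun by 2.49, and the camera call was lost at adjusted p = 0.059 with an estimated correlation. Lysosome genes fell 19 of 40 with 1 rise (3 and 23 adjusted over the list alone), Psap by 1.56, Ctsl by 1.44 and Hexa by 0.91, with Ppt1 higher (0.72). Disease-associated microglia genes fell 11 of 24 with 2 rises (3 and 11 adjusted over the list alone), Gpnmb (-1.48) and Clec7a (-2.67) down and Cst7 (1.91) up. MHC class I genes fell 4 of 13 with 0 rises (0 and 5 adjusted over the list alone), H2-D1 by 1.11 and H2-K1 by 0.78. Border-associated macrophage markers rose 8 of 14 with 1 fall (10 and 1 adjusted over the list alone). Microglia signature genes were split, 4 of 25 higher and 3 lower (5 and 5 adjusted over the list alone), Ltc4s up by 2.34 and Entpd1 down (-1.34).

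This comparison called 1334 genes, 611 higher and 723 lower, against 728 and 547 with no scaling factors. The total depended on the libraries and the fit used. It was 819 without iPSC-derived day 3 replicate 1, 858 without day 12 replicate 1, 780 without day 12 replicate 2 and 324 in a fit on only the groups compared.

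The same day 12 question in bone marrow-derived macrophages showed rises of Cx3cr1, Tmem119, Fcrls and P2ry12 (n = 3 against n = 3). Cx3cr1 went from 1.29 ± 1.29 to 1166 ± 76.9 CPM (SD, n = 3; log2 fold change 9.84 ± 0.59 SE, adjusted p = 5.8e-10). Its 3 day 0 libraries held 2.58, 0 and 1.3 CPM. Tmem119 went from 0.0864 ± 0.0748 to 156 ± 10.6 CPM, a count ratio of 1880 (95% interval 519 to 15500). Fcrls rose by 2.72 ± 0.27 to 3954 ± 220 CPM, P2ry12 by 1.45 ± 0.26 and C1qa by 2.97 ± 0.20. Mki67 rose by 3.50 ± 0.38 to 140 ± 23.6 CPM. Olfml3 (8.51 ± 0.52), Sparc (6.92) and the phosphatase-domain gene Pald1 (9.29 ± 0.64) rose, and Pmepa1, a TGF-beta-induced gene, had a count ratio of 2300 (413 to 91000). Fpr1, a formyl peptide receptor gene, had a count ratio of 1520 (421 to 12600). Count ratios were 631 (174 to 5220) for Ccnb2, 284 (97 to 1380) for Nid1 and 286 (78.9 to 2360) for Hmmr, and Pimreg was at least 163-fold higher.

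Clec10a and Slc40a1 were among the genes that fell in bone marrow-derived cells by day 12. Clec10a, a lectin gene of alternatively activated macrophages, fell from 337 ± 35.5 to 9.64 ± 2.01 CPM (-5.13 ± 0.44, adjusted p = 1.7e-08). The iron exporter gene Slc40a1 fell from 1467 ± 88.0 to 88.6 ± 11.4 CPM (-4.05 ± 0.38). Mgl2 (-6.54 ± 1.05), Pira2 (-5.36 ± 0.47), Mcoln3 (-5.24 ± 0.66), Vwf (-5.21 ± 0.47), Gprc5c (-4.70 ± 0.68), Ighm (-3.99 ± 0.61) and Mmp27 (-3.92 ± 0.46) fell, and Klk1b11 was at least 301-fold lower. Reads that map to several places were left out of the counts, so genes in families with shared sequence, such as Klk1b11, Pira2 and Mgl2, are counted only from reads unique to them. H2-Aa (-1.95 ± 0.47) and Cd74 (-1.65 ± 0.41) fell, and Tnf rose by 3.37 ± 0.35. Trem2, Csf1r (adjusted p = 0.13), Sall1 (0.13), Il1b (0.061), Mrc1, Gpr34, Ccr2 and Adgre1 did not pass.

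By group, 33 of 35 cell cycle genes rose in bone marrow-derived cells and 1 fell: the replication helicase gene Mcm2 by 3.03 ± 0.23 and Tpx2 by 3.96, with Cenpa lower (-2.40). The camera call on that list was lost at adjusted p = 0.096 with an estimated correlation. Interferon response genes rose 24 of 30 with 2 falls (26 and 2 adjusted over the list alone), Oasl1 by 3.91 ± 0.41, and Oas1a by 2.48, with Gbp3 (-1.04) and Gbp2 (-1.13) lower, and the call was lost at adjusted p = 0.15 with an estimated correlation. Glycolysis and hypoxia genes rose 17 of 30 with 2 falls (18 and 2 adjusted over the list alone), the glucose transporter gene Slc2a1 by 2.64 ± 0.28, Pkm by 1.57 and P4ha1 by 1.97, with Ndrg1 (-1.45) and Vegfa (-1.94) lower. TGF-beta response genes rose 15 of 21 with 0 falls (16 and 1 adjusted over the list alone), Skil by 2.90 and Id2 by 2.14, and this list and the chemokine genes (11 of 25 higher, 1 lower; 12 and 1 adjusted over the list alone) kept their camera calls with an estimated correlation. Ccl12 (7.18) and Ccl8 (6.54) rose and Ccl6 (-1.08) fell. Microglia signature genes rose 15 of 25 with 1 fall (17 and 2 adjusted over the list alone), Tgfbr1 by 2.32, with Entpd1 lower (-1.30); that call was lost at adjusted p = 0.096 with an estimated correlation. ATF4 genes rose 11 of 22 with 3 falls (14 and 3 adjusted over the list alone), Mthfd2 by 3.19. Lysosome genes fell 16 of 40 with 4 rises (4 and 19 adjusted over the list alone), Psap by 2.23 ± 0.11 and Ctsb by 1.16.

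Other-cell transcripts were counted in these libraries too. Gfap rose by 6.53 ± 0.77 log2 units to 16.6 ± 1.05 CPM, Col3a1 by 5.56 ± 1.11 from 0, 4.41 and 0 CPM in the 3 day 0 libraries, Dcn by 4.90 ± 0.98 and Tubb3 by 4.21 ± 0.69, and Stmn2 had a count ratio of 110 (95% interval 19.5 to 4390). Astrocyte genes rose 10 of 12 with 1 fall (Aldoc, -1.08), Slc1a3 by 5.45. Fibroblast genes rose 9 of 12 with 0 falls (11 and 0 adjusted over the list alone), neuron genes 9 of 19 with 0 falls (9 and 1 adjusted over the list alone), Map2 by 5.47, and oligodendrocyte genes 4 of 12 with 0 falls.

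Bone marrow-derived cells had 3568 genes called at day 12, 2206 higher and 1362 lower. With no scaling factors the split was 2820 and 882 and the all-gene median moved by 0.17.

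At day 3 against day 0, bone marrow-derived cells showed an inflammatory rise (n = 3 against n = 3). Ccl5, a T-cell chemokine gene, went from 1.49 ± 0.729 to 454 ± 89.0 CPM (log2 fold change 8.24 ± 0.63). Il1b, an inflammatory cytokine gene, rose by 6.18 ± 1.03, Tnf by 2.15 and the arginase gene Arg1 by 8.47, and Nos2, nitric oxide synthase, was at least 147-fold higher. Cx3cr1 rose by 7.10 ± 0.55, Olfml3 by 8.73 ± 0.52, C1qa by 2.87 ± 0.20 and Fcrls by 0.76, Tmem119 had a count ratio of 594 (95% interval 164 to 4910), and P2ry12 (0.09, adjusted p = 0.87) did not pass. Klra2, Marco and Tarm1 were at least 475-fold, 423-fold and 296-fold higher, and Fpr1 had a count ratio of 3660 (1010 to 30200). Klk1b11 was at least 272-fold lower, and Cbr2 (-5.92 ± 0.55), Mgl2 (-5.76 ± 1.00) and Ighm (-5.43 ± 0.66) fell.

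Interferon response genes rose 26 of 30 with 0 falls at day 3, Oasl1 by 5.45 ± 0.41 and Oas1a by 2.52. Genes of glycolysis and hypoxia rose 23 of 30 with 0 falls (25 and 0 adjusted over the list alone), Slc2a1 by 3.95 ± 0.29, Pkm by 2.41 and Aldoa by 1.51. Inflammatory NF-kB genes rose 17 of 28 with 0 falls (19 and 0 adjusted over the list alone), Sod2 by 2.36. MHC class I genes rose 10 of 13 with 0 falls (11 and 0 adjusted over the list alone), H2-K1 by 1.73 and Tap1 by 2.31. LXR targets rose 11 of 14 with 0 falls (13 and 0 adjusted over the list alone), TGF-beta response genes 13 of 21 with 0 falls, Skil by 2.82, and monocyte genes 10 of 17 with 1 fall, the haptoglobin gene Hp by 7.51 with Itga4 lower (-1.34). Microglia signature genes rose 12 of 25 with 3 falls (13 and 3 adjusted over the list alone), with Entpd1 (-1.31), Bin1 (-1.11) and Slco2b1 (-1.12) lower. Lysosome genes fell 13 of 40 with 6 rises (6 and 14 adjusted over the list alone), Ctsb by 1.70, and cholesterol biosynthesis genes fell 10 of 23 with 0 rises (1 and 13 adjusted over the list alone). Neuron genes rose 13 of 19 with 0 falls (15 and 0 adjusted over the list alone), Tubb3 by 5.77 ± 0.69, and fibroblast genes had 0 changes. The total was 2775 genes, 1783 higher and 992 lower. A fit on only the groups compared called 2141 and 1731, and without day 0 replicate 2 the lower count was 640.

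By day 6 in bone marrow-derived cells, P2ry12 had risen by 1.03 ± 0.26 log2 units to 69.0 ± 4.27 CPM (n = 3 against n = 3). Cx3cr1 rose by 9.06 ± 0.57, Fcrls by 2.23 ± 0.27, C1qa by 2.79 and Mki67 by 2.06 ± 0.36. Tmem119 had a count ratio of 691 (95% interval 191 to 5710), Fpr1 of 2270 (628 to 18700) and Sall1 of 44.7 (7.63 to 1810). Klra2, a lectin-like receptor gene, was at least 215-fold higher, Klk1b11 at least 234-fold lower, and Siglech at least 26.2-fold lower. Mgl2 (-6.20 ± 1.04), Cbr2 (-5.95 ± 0.56) and Ighm, an immunoglobulin heavy chain gene, (-4.87 ± 0.65) fell. Cell cycle genes rose 28 of 35 with 1 fall (29 and 1 adjusted over the list alone), Mcm2 by 2.36 with Cenpa lower (-2.85). Interferon response genes rose 25 of 30 with 0 falls, glycolysis and hypoxia genes 20 of 30 with 1 fall (22 and 1 adjusted over the list alone), P4ha1 by 2.32 and Slc2a1 by 3.52 with Ndrg1 lower (-0.69), and TGF-beta response genes 14 of 21 with 0 falls (15 and 0 adjusted over the list alone). Microglia signature genes rose 16 of 25 with 3 falls (17 and 3 adjusted over the list alone). Astrocyte genes rose 9 of 12 with 0 falls (10 and 0 adjusted over the list alone), Gfap by 5.83 ± 0.77 and Slc1a3 by 5.39, and fibroblast genes 6 of 12 with 0 falls (7 and 0 adjusted over the list alone). Of 2933 genes called, 1899 were higher and 1034 lower, against 2328 and 673 with no scaling factors and an all-gene median moved by 0.13. A fit on only the groups compared called 2195 and 1880, and without day 6 replicate 3 the lower count was 644.

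Between day 3 and day 12, Mki67 rose and the chemokine gene Ccl5 fell in bone marrow-derived cells (n = 3 against n = 3). Mki67 rose by 3.11 ± 0.37 log2 units, Cx3cr1 by 2.74 ± 0.39, Fcrls by 1.96, Tmem119 by 1.65 ± 0.38 and P2ry12 by 1.36 ± 0.26. Ccl5 fell by 7.03 ± 0.57 (adjusted p = 1.1e-07) to 3.44 ± 0.845 CPM, and the protease inhibitor gene Slpi (-6.87 ± 1.02), Mcemp1 (-6.78 ± 1.18) and Tarm1 (-6.76 ± 0.87) fell too. Rtn4rl1 (5.46 ± 0.55), Slco4a1 (4.82 ± 1.04), Pmepa1 (4.69 ± 0.41) and the kinetochore gene Knl1 (4.39 ± 0.60) rose. Cell cycle genes rose 33 of 35 with 0 falls (34 and 0 adjusted over the list alone), Mcm2 by 2.70, and microglia signature genes 12 of 25 with 1 fall (15 and 1 adjusted over the list alone), Golm1 by 1.98 and Ltc4s by 3.02 with Selplg lower (-0.73). Glycolysis and hypoxia genes fell 18 of 30 with 0 rises (0 and 20 adjusted over the list alone), Aldoa by 1.37 and Pfkfb3 by 1.48. Monocyte genes fell 6 of 17 with 0 rises (0 and 7 adjusted over the list alone), Thbs1 by 2.77 and Cd44 by 1.34. Inflammatory NF-kB genes fell 9 of 28 with 4 rises (5 and 12 adjusted over the list alone), Sod2 by 2.22, with the camera call lost at adjusted p = 0.18 with an estimated correlation. Interferon response genes fell 12 of 30 with 0 rises (1 and 15 adjusted over the list alone), and NRF2 genes 7 of 17 with 0 rises (0 and 11 adjusted over the list alone), the heme oxygenase gene Hmox1 by 2.06.

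That comparison called 1267 genes, 630 higher and 637 lower, against 790 and 505 with no scaling factors. It was 790 in all without bone marrow-derived day 3 replicate 3 and 2751 in a fit on only the groups compared.

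How far did the 2 sources change alike by day 12? Log2 fold changes against day 0 correlated at r = 0.341 over 15000 genes. Without the 2042 genes under 1 CPM in both day 0 groups r was 0.011. Genes are not independent replicates, so no p-value is attached. Of 1474 genes called in both sources, 688 rose in both (308.7 expected from the margins) and 324 fell in both (145.9 expected). Another 193 rose in iPSC-derived and fell in bone marrow-derived cells (190.6 expected), and 269 did the reverse (236.3 expected). The share with 1 direction was 49.0% at day 3, 63.5% at day 6 and 68.7% at day 12. Without the genes under 1 CPM in both day 0 groups the day 12 share was 60.9%. There 389 genes rose in both sources (212.1 expected) and 326 fell in both (168.2 expected). Cx3cr1, Tmem119, Fcrls, P2ry12 and C1qa were among the genes that rose in both, and Oasl1, Slc2a1 and Mthfd2 fell in iPSC-derived and rose in bone marrow-derived cells.

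**Figure D4:**
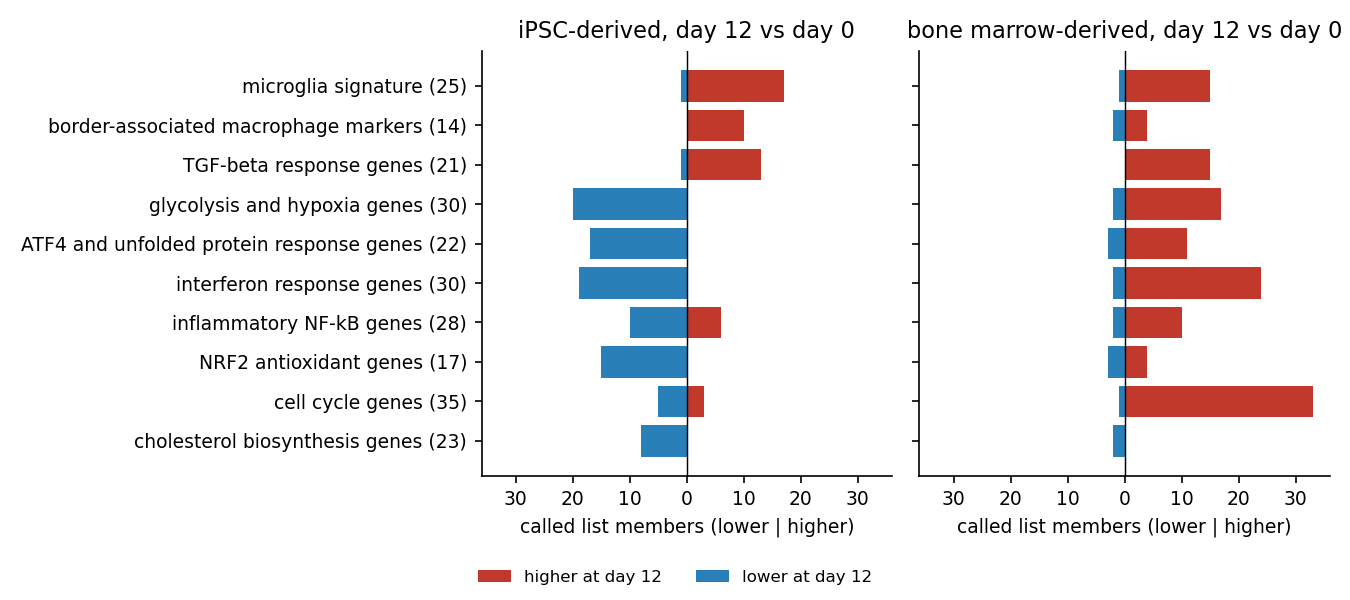
Called members of 10 gene lists at day 12 against day 0, by source. Bars to the left count members that fell and bars to the right members that rose.

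The next question is how the 2 sources differed before co-culture (day 0, n = 3 against n = 3). The labels do not give library batches. Library codes form separate runs for the 2 sources, and run by replicate number in iPSC-derived and by day in bone marrow-derived cells. If these runs were batches, every difference between the sources could hold a batch difference. So could changes with day in bone marrow-derived cells. The labels do not allow these to be separated. Cx3cr1 was 90.9 ± 37.0 CPM in iPSC-derived and 1.29 ± 1.29 CPM in bone marrow-derived macrophages (log2 difference 6.16 ± 0.54). Olfml3 was higher in iPSC-derived cells by 5.61 ± 0.54, Tnf, a cytokine gene, by 5.08 ± 0.36 and Mki67 by 2.78 ± 0.37. Fcrls was lower by 2.51 ± 0.27, and P2ry12 (-0.57, adjusted p = 0.093) did not pass. Apoe (-1.57), Csf1r (-1.83), Cd74 (-2.84), H2-Aa (-2.68 ± 0.49) and the monocyte chemokine receptor gene Ccr2 (-5.08 ± 0.54) were lower. Lin28b, an RNA-binding gene of fetal blood cells, was at least 92.4-fold higher and Tmem119 had a count ratio of 20.0 (95% interval 5.24 to 170). The day 0 libraries held 1.53, 0 and 3.43 CPM of Tmem119 in iPSC-derived and 0.129, 0 and 0.13 CPM in bone marrow-derived cells. The sources thus overlapped for this gene.

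The largest day 0 differences between sources were in genes near absent in 1 of them. Flnc, an actin cross-linker gene, had a count ratio of 5940 (1070 to 235000), Igf2bp1 of 1990 (356 to 78500) and Adamts1 of 1350 (374 to 11200). Cspg4, Gem, Pkp2, Aqp9, Pimreg, Marco and Cpne8 were at least 463-fold, 446-fold, 337-fold, 304-fold, 229-fold, 172-fold and 162-fold higher in iPSC-derived cells. Lower by at least 828-fold, 798-fold and 242-fold were the hemoglobin scavenger receptor gene Cd163, Nxpe5 and Slc9a7. Adam19 (-9.04 ± 1.09), AI662270 (-8.08 ± 0.46), Mgl2 (-7.98 ± 1.18), Ldlrad3 (-7.45 ± 0.89), Pdgfc (-7.29 ± 0.85) and Clec10a (-7.03 ± 0.50) were lower, as was Klk1b11 at a count ratio of 267 (90.8 to 1300).

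Day 0 groups differed by family as well. Genes of glycolysis and hypoxia were higher in iPSC-derived cells for 22 of 30 and lower for 2, Aldoa by 2.34 and Slc2a1 by 4.63, with Vegfa (-2.78) and Car9 (-2.41) lower. ATF4 genes were higher for 18 of 22 and lower for 0 (19 and 0 adjusted over the list alone), Mthfd2 by 5.67 ± 0.29, Psat1 by 5.23 and Atf4 by 3.14. Interferon response genes were higher for 25 of 30 and lower for 0 (27 and 0 adjusted over the list alone), Oasl1 by 7.87 ± 0.42 and Usp18 by 4.39, with the camera call lost at adjusted p = 0.079 with an estimated correlation. Cell cycle genes were higher for 30 of 35 and lower for 1, Tpx2 by 4.02 with Cenpa lower (-2.81), and that call was lost at adjusted p = 0.27 with an estimated correlation. Fetal and imprinted genes were higher for 7 of 13, Igf2bp3, an RNA-binding gene of fetal cells, by 3.55 ± 0.19 and Peg3 by 4.86. General macrophage genes were lower for 14 of 21 and higher for 1 (1 and 15 adjusted over the list alone), Mertk by -2.23 and Lyz2 by -3.55, with Fcgr1 higher (0.62). MHC class II genes were lower for 9 of 10, H2-DMa by -4.59 ± 0.25, and border-associated markers for 10 of 14, Stab1 by -2.29. Cholesterol biosynthesis genes were higher for 16 of 23 (17 adjusted over the list alone). Microglia signature genes were split, 8 of 25 higher and 9 lower (10 and 10 adjusted over the list alone). The day 0 total was 5401 genes, 2829 higher and 2572 lower in iPSC-derived cells.

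At day 3 of co-culture the sources differed in antigen presentation genes, among others (n = 3 against n = 3). Cd74, the MHC class II invariant chain gene, was lower in iPSC-derived cells (log2 difference -5.11 ± 0.48), H2-Aa had a count ratio of 1860 (95% interval 514 to 15400) in that direction, and Il1b was lower (-6.36). Cx3cr1 was higher by 2.85 ± 0.40, P2ry12 by 1.24 ± 0.26 and Fcrls by 1.02, C1qa was lower (-0.93), and Tmem119 (-1.03, adjusted p = 0.069) did not pass. Klra2, Napsa, Clec2i and Spic were at least 528-fold, 498-fold, 430-fold and 269-fold lower. The protease gene Adamts1 had a count ratio of 1750 (314 to 69300), and C2 (7.90 ± 0.80), Tln2 (7.68 ± 0.49) and Asb10 (7.38 ± 0.87) were higher. Lysosome genes were higher for 26 of 40 and lower for 4 (28 and 4 adjusted over the list alone), Ctsd by 2.20 and Ctsb by 1.71. Glycolysis and hypoxia genes were lower for 26 of 30 and higher for 0, Vegfa by -6.29 and Aldoa by -1.10. Disease-associated microglia genes were higher for 21 of 24 and lower for 3, Igf1 by 2.71 with Cst7 lower (-5.69). MHC class I genes were lower for 10 of 13 (11 adjusted over the list alone), H2-K1 by -1.93, and MHC class II genes for 8 of 10 (9 adjusted over the list alone). Monocyte genes were lower for 10 of 17 (11 adjusted over the list alone), Thbs1 by -3.99 and Ccr2 by -4.94. Inflammatory NF-kB genes were lower for 17 of 28 and higher for 2 (2 and 19 adjusted over the list alone), Sod2 by -2.39. Cell cycle genes were higher for 21 of 35 and lower for 0 (25 and 0 adjusted over the list alone), with the camera call lost at adjusted p = 0.30 with an estimated correlation. The total was 2679, 1341 higher and 1338 lower, against 922 and 1987 with no scaling factors and an all-gene median moved by -0.20.

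At day 6 of co-culture P2ry12 (0.26, adjusted p = 0.61), Fcrls (0.06), Tmem119 (-0.68) and Cx3cr1 (1.01, adjusted p = 0.083) did not pass between the sources (n = 3 against n = 3). Cd74 was lower in iPSC-derived cells (-6.27 ± 0.52). H2-Eb1, an MHC class II chain gene, was at least 1030-fold lower, as were Clec2i, AI662270 and Mefv by at least 517-fold, 503-fold and 424-fold. Msln had a count ratio of 527 (95% interval 94.3 to 20900), Col5a2 of 412 (114 to 3410), and Adamts1 (7.98 ± 0.45) and the vascular growth factor receptor gene Flt1 (6.47 ± 1.00) were higher. Fetal and imprinted genes were higher for 9 of 13 and lower for 0 (10 and 0 adjusted over the list alone), Igf2bp3 by 2.91. MHC class I genes were lower for 10 of 13 (11 adjusted over the list alone), H2-K1 by -2.20, MHC class II genes for 8 of 10, and glycolysis and hypoxia genes for 18 of 30 (20 adjusted over the list alone), with 0 higher in each. Disease-associated microglia genes were higher for 15 of 24 and lower for 3 (15 and 4 adjusted over the list alone). Fibroblast genes were higher for 6 of 12 and lower for 0 (8 and 0 adjusted over the list alone), Col1a1 by 4.95 ± 0.98 and Col1a2 by 3.84. Interferon response genes were lower for 16 of 30 and higher for 0 (0 and 20 adjusted over the list alone), with the camera call lost at adjusted p = 0.11 with an estimated correlation. In all 1982 genes were called, 1048 higher and 934 lower, against 806 and 1182 with no scaling factors. Without bone marrow-derived day 6 replicate 2 the higher count was 632.

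At day 12 of co-culture 4 microglial genes did not pass between the sources (n = 3 against n = 3). P2ry12 was 88.7 ± 31.9 CPM in iPSC-derived and 92.1 ± 5.31 CPM in bone marrow-derived cells (log2 difference -0.05 ± 0.25 SE, adjusted p = 0.94). Tmem119 (-0.66 ± 0.37, adjusted p = 0.32), Fcrls (-0.14 ± 0.25, 0.81) and Cx3cr1 (-0.36 ± 0.37, 0.64) were the others. Olfml3 was higher in iPSC-derived cells by 1.03 ± 0.30 and Apoe by 1.28 ± 0.18, and Mki67 was lower (-1.40 ± 0.34, adjusted p = 0.0085). Spp1, which encodes the secreted protein osteopontin, was 56140 ± 44400 CPM in iPSC-derived and 1380 ± 191 CPM in bone marrow-derived cells (5.35 ± 0.46, adjusted p = 1.7e-07). The 3 iPSC-derived libraries held 48300, 104000 and 16100 CPM of Spp1, and the difference was 4.59 without replicate 2. Adamts1, an extracellular protease gene, was higher by 6.48 ± 0.37 and Colec12, a scavenger receptor gene, by 4.95 ± 0.29. Tcim (7.97 ± 0.83), Car2 (6.24 ± 1.46, and 8.40 without bone marrow-derived replicate 1), Nrap (6.04 ± 0.71), C2 (6.03 ± 0.74), Tln2 (5.64 ± 0.43), Flt1 (5.48 ± 0.89) and Itgb3 (4.98 ± 0.92) completed the 10 largest.

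Ccr2 and Cd163 were among the genes lower in iPSC-derived cells at day 12. Ccr2 was 0.257 ± 0.198 CPM against 44.9 ± 1.36 CPM (-7.44 ± 0.63, adjusted p = 1.1e-08), and Cd163 had a count ratio of 654 (95% interval 117 to 25900). Count ratios in the same direction were 2030 (363 to 80100) for the lectin-like gene Clec2i, 282 (96.4 to 1370) for H2-Aa and 208 (71 to 1010) for Sirpb1c. AI662270 (-7.93 ± 0.46), Vill (-7.00 ± 0.64), Tspan32 (-6.97 ± 0.56), Tgtp2 (-6.49 ± 0.75), H2-Eb1 (-6.22 ± 0.73), Cd74 (-3.38 ± 0.45) and Ptprc (-0.93) were lower. Lin28b was at least 52.4-fold higher.

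Of 25 microglia signature genes, 6 were higher in iPSC-derived cells at day 12 and 3 lower, Sall3 by 3.12 with Selplg (-1.17) lower. MHC class II genes were lower for 7 of 10, H2-DMa by -3.46 ± 0.23, and MHC class I genes for 9 of 13 (10 adjusted over the list alone), H2-K1 by -1.43 ± 0.11 and Tap1 by -1.55, with 0 higher in either. Lysosome genes were higher for 21 of 40 and lower for 3 (24 and 4 adjusted over the list alone), Ctsl by 1.31 with Psap (-0.99) and Ctsh (-1.89) lower. Fetal and imprinted genes were higher for 7 of 13 and lower for 0, Igf2bp3 by 2.57 ± 0.18 and Igf2bp1 by 2.86. Disease-associated microglia genes were higher for 10 of 24 and lower for 3 (13 and 3 adjusted over the list alone), Igf1 by 1.46 with Cst7 (-2.92) and Itgax (-3.34) lower. Fatty acid oxidation and PPAR genes were higher for 6 of 20 (7 adjusted over the list alone), Plin2 by 1.85 and Lpl by 1.25. Chemokine genes were lower for 8 of 25 and higher for 3 (3 and 13 adjusted over the list alone), Ccr1 by -3.17 with Ccl3 higher (1.99). Monocyte genes were lower for 4 of 17 (1 higher and 4 lower adjusted over the list alone), Thbs1 by -2.60. All of these lists but the microglia one kept a camera call with an estimated correlation. Immediate early genes were higher for 10 of 19 and lower for 0 (13 and 0 adjusted over the list alone), Atf3 by 2.78, with the call lost at adjusted p = 0.25 with an estimated correlation. Cell cycle genes were lower for 6 of 35 and higher for 0 (0 and 13 adjusted over the list alone), Top2a by -1.52. The astrocyte list had 0 differences, the neuron list 1 higher and 1 lower, and the fibroblast list 1 higher, Col1a2 by 2.34. The total at day 12 was 1465 genes, 754 higher and 711 lower, against 416 and 1235 with no scaling factors and an all-gene median moved by -0.22.

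The number of genes that differed between sources went from 5401 at day 0 to 2679 at day 3, 1982 at day 6 and 1465 at day 12. The root mean square log2 difference over all tested genes went from 1.47 at day 0 to 0.996 at day 12, or 67.7% of its day 0 size. Called at all 4 days in 1 direction were 494 genes, 261 higher in iPSC-derived cells, among them Adamts1, Colec12 and Igf2bp3, and 233 lower, among them Cd163, Cd74, H2-DMa and Ccr2. Of the genes called at day 0, 4436 were not called at day 12. Another 965 were called at both (527.5 expected), 764 in the same direction and 201 in the opposite one, and 500 were called at day 12 only.

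**Figure D5:**
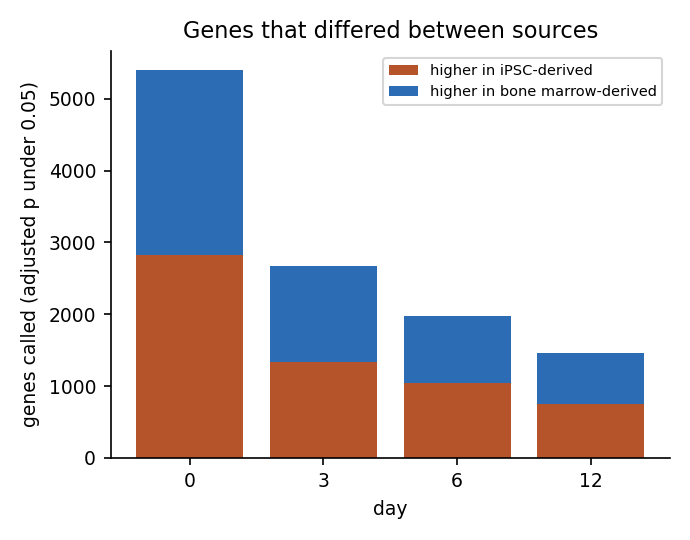
Genes called different between iPSC-derived and bone marrow-derived macrophages at each day. Bars are split by the source in which the gene was higher.

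Whether the change from day 0 differed between sources was tested as an interaction (iPSC-derived change minus bone marrow-derived change, n = 3 in each of 4 groups). At day 12, Oasl1 had a difference in change of -8.67 ± 0.52 log2 units, Mthfd2 of -6.61 ± 0.37, Slc2a1 of -4.15, Tnf of -4.57 ± 0.46 and Cx3cr1 of -6.52 ± 0.66. Oasl1 went from 237 ± 8.82 to 8.80 ± 4.16 CPM in iPSC-derived and from 1.01 ± 0.261 to 15.2 ± 6.16 CPM in bone marrow-derived cells. Fcrls (2.36 ± 0.37), Apoe (2.85 ± 0.26) and Slco2b1 (2.63) changed more upward in iPSC-derived cells, while P2ry12 (0.52, adjusted p = 0.36) did not pass. Interferon response genes had a more negative change in iPSC-derived cells for 27 of 30 and a more positive one for 0 (0 and 30 adjusted over the list alone), Usp18 by -4.33 and Oas1a by -2.98. Genes of glycolysis and hypoxia did so for 22 of 30 with 0 positive (0 and 24 adjusted over the list alone), Aldoa by -1.85 ± 0.17, and ATF4 genes for 15 of 22 with 0 positive (0 and 17 adjusted over the list alone), Phgdh by -8.46. General macrophage genes were more positive for 11 of 21 and negative for 1 (14 and 1 adjusted over the list alone), Mertk by 2.03 and Csf1r by 1.44 with Ptprc negative (-0.69). These 4 lists kept their camera calls with an estimated correlation. Cell cycle genes were negative for 31 of 35 with 1 positive (1 and 32 adjusted over the list alone), Tpx2 by -4.77 with Cenpa positive (2.05), and that call was lost at adjusted p = 0.12 with an estimated correlation. Microglia signature genes were split, 6 of 25 positive and 6 negative (6 and 8 adjusted over the list alone). The total was 3008 genes, 1361 positive and 1647 negative, against 846 and 2473 with no scaling factors and an all-gene median moved by -0.30.

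The day 3 interaction called 3075 genes, 1354 positive and 1721 negative. Aldoa had a difference in change of -3.44 ± 0.17 log2 units, the pyruvate kinase gene Pkm of -4.05, Oasl1 of -8.62 and Sod2, a superoxide dismutase gene, of -3.46, while P2ry12 (1.81 ± 0.37), Fcrls (3.53) and Apoe (2.89) were positive. Glycolysis and hypoxia genes were negative for 27 of 30 (28 adjusted over the list alone), Tpi1 by -3.92, interferon response genes for 28 of 30, and ATF4 genes for 15 of 22 (16 adjusted over the list alone), with 0 positive in each. Inflammatory NF-kB genes were negative for 22 of 28 with 1 positive (1 and 24 adjusted over the list alone). Lysosome genes were positive for 22 of 40 with 1 negative (23 and 4 adjusted over the list alone), Psap by 2.31, and disease-associated microglia genes for 13 of 24 with 2 negative (14 and 4 adjusted over the list alone), Ctsb by 2.39. With no scaling factors the split was 914 and 2425 and the all-gene median moved by -0.27.

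The day 6 interaction called 2951 genes, 1293 positive and 1658 negative. The itaconate enzyme gene Acod1 had a difference in change of -10.38 ± 0.84 log2 units, Oasl1 of -8.98, Mthfd2 of -6.34 and Aldoa of -3.01. Interferon response genes were negative for 30 of 30. Genes of glycolysis and hypoxia were negative for 23 of 30 (27 adjusted over the list alone), ATF4 genes for 15 of 22 (17 adjusted over the list alone) and MHC class I genes for 7 of 13 (9 adjusted over the list alone), H2-K1, a class I heavy chain gene, by -1.64, with 0 positive in each. Cell cycle genes were negative for 29 of 35 with 1 positive (1 and 30 adjusted over the list alone), and the camera call was lost at adjusted p = 0.14 with an estimated correlation. With no scaling factors the split was 931 and 2116 and the all-gene median moved by -0.18.

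Across all comparisons the camera test called 269 pairs of list and comparison with its preset correlation and 99 with an estimated one.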

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

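The test of carry-over from the co-culture for the neural and connective-tissue transcripts, the setting with no scaling factors and the limit to genes with a mean log2 CPM of at least 6 were chosen after seeing the result.

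These results were picked out because the effect differed between the 2 sources by a tested interaction. The change from day 0 differed for 3075 genes at day 3, 2951 at day 6 and 3008 at day 12. Median differences in change at day 12 (iPSC-derived minus bone marrow-derived, log2) were 0.78 for general macrophage markers, -2.93 for interferon response genes, -2.08 for glycolysis and hypoxia genes and -1.87 for ATF4 and unfolded protein response genes. The largest single values were 9.54 for Nxpe5, 8.89 for Bmp2, 8.73 for Slc9a7 and 8.31 for Pdgfc, and on the negative side -12.39 for Aqp9, -12.12 for Pimreg, -11.84 for Flnc and -10.65 for Ccnb2. Each of these genes was near or at 0 counts in at least 1 group, so the fitted values depend on the prior count and are no bound.

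The first pattern is the neural and connective-tissue transcripts in the co-cultured libraries. If they were carry-over from the co-culture, genes silent at day 0 should appear far more often in these 4 lists than in control lists of other blood and vessel cells. Silent means at most 3 counts over the 6 day 0 libraries, and appearing means more than 18 over the 18 co-cultured ones. Of 25 silent members 21 appeared (84%, 95% interval 63.9 to 95.5), against 1 of 28 control members (3.6%, 0.1 to 18.3). Carry-over and the macrophages' own expression could both give this difference of 80.4 percentage points. Neuron genes made up 15 of the 25 (12 appeared) and fibroblast genes only 2 (2 appeared). The share thus says little about connective-tissue transcripts. In 2 lists outside both arms, 7 of 9 silent pluripotency genes (77.8%) and 7 of 10 neural progenitor genes (70%) appeared too. The macrophages' own expression cannot be told apart from it by covariation within groups: the mean pairwise correlation of the 12 fibroblast genes was 0.22 (permutation p = 1e-04), between the limits of 0.1 and 0.3 set for that list, that of neuron genes 0.135 (p = 0.001) and that of astrocyte genes 0.038 (p = 0.14).

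A second pattern is that fewer genes differ between the sources at day 12 than at day 0. Larger replicate spread at day 12 would leave the size of the difference near its day 0 value once replicate variance is removed, but it was 59.4% of it (54.1 to 65.6 without any 1 library). Carry-over of the same RNA into both sources, if a small share of the counts, would move highly expressed genes little. The difference among the 2771 most expressed genes would then stay near its day 0 size, but it was 47.6% of it (42.7 to 54.1 without any 1 library). Larger replicate spread thus does not account for the fall, and neither does carry-over of a small share of RNA. That share was not estimated, and a large one could bring highly expressed genes together too. A change of both sources in the same surroundings remains possible. These values could not separate it from loss of day 0 culture effects.

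The third pattern is the gene lists that changed in opposite directions in the 2 sources. With no library scaling factors all 3 list medians kept their sign and the largest move was 0.3 log2 units. The all-gene median of the interaction moved by -0.30 too, so the move was shared with other genes. It made the 3 medians larger in size. With each of 12 libraries left out in turn, every median kept at least 91.2% of its size, with ranges of -3.11 to -2.67 for interferon, -2.16 to -2.04 for glycolysis and -2.07 to -1.75 for ATF4 genes. The scaling factors used do not account for these medians, and neither does 1 deviant library. A larger scaling error was not tested, as the counts hold no spike-in. The median log2 differences between the sources in the interferon, glycolysis and ATF4 lists were 2.5, 2.22 and 2.26 at day 0. At day 12 they were -0.49, -0.08 and 0.16. For each gene the interaction is the day 12 difference minus the day 0 difference, so these medians mostly hold the loss of the day 0 difference. What set the day 0 levels was not tested.

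Chance was weighed by splitting the libraries of each comparison again. With 3 against 3 only 10 splits exist, too few to exclude chance, and in all 12 such comparisons the real split was the only 1 as large. The highest other split called 0, 1, 34 and 39 genes for iPSC-derived day 3, 6 and 12 and day 12 against day 3, and 0, 0, 1 and 1 for bone marrow-derived cells. Between the sources it was 1, 0, 0 and 2 at days 0, 3, 6 and 12. For the interactions 4 of 100 splits were as large at day 3, 5 at day 6 and 6 at day 12, and the highest other split called 3274, 3574 and 4668 genes. Only the share at day 3 lies under the limit of 0.05 set for chance, but these shares cannot decide the question. Of the other splits, 11, 10 and 10 kept the day 0 sources together and so still held the day 0 difference between them. The 3, 4 and 5 other splits as large were all among these. The split with 4668 genes at day 12 was the real grouping with the day 0 sources swapped. Splits that kept no day together called at most 1 gene.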

How the results depend on the processing

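The alternatives with no scaling factors, with genes under 1 CPM at day 0 left out and with mean log2 CPM of at least 6 were chosen after seeing the result. A fit on only the groups compared moved 5 totals by over 1.5 times: 1849, 1938 and 2106 for iPSC-derived day 3, 6 and 12 (main 2907, 3804 and 3706), and for day 12 against day 3, 324 in iPSC-derived (1334) and 2751 in bone marrow-derived cells (1267). It tests with fewer samples and its own dispersion, and it lowered the iPSC-derived totals between days and raised the bone marrow-derived ones. At day 12 against day 0 it called 2106 and 3975 genes (main 3706 and 3568). Replicates differed more in iPSC-derived cells at each day, by 1.09 against 0.882 log2 units (root mean square) at day 12. A dispersion shared by both sources may thus call too many genes in iPSC-derived and too few in bone marrow-derived cells. Without 1 library those 2 day 12 against day 3 totals ran from 780 to 1503 and from 790 to 960. List tests called 99 pairs with an estimated correlation, against 269. The correlation of day 12 changes between sources (0.341) was 0.211 at mean log2 CPM of at least 3, 0.011 with genes under 1 CPM left out, and 0.276 to 0.367 without 1 library. The day 12 distance between sources (67.7% of day 0) was 69.824% with prior count 0.5, 72.272% over the 1000 most variable genes, 51.569% at mean log2 CPM of at least 6, and 65.801% to 75.111% without 1 library. A replicate block, for the numbers shared between groups, gave 3694 genes for iPSC-derived day 12. Deviations from group means correlated at a mean of 0.043 (iPSC-derived) and 0.012 (bone marrow-derived) between libraries of the same number. Between different numbers the means were -0.021 and -0.006. Of 24 libraries, 18 correlated best with 1 of their own number, although only 18 pairs per source shared a number and 36 did not. These values point to a weak shared structure, for which no test was run. The main tests are unpaired because the labels do not say what a number shares. Of 8293 values for named genes under alternatives, 7929 stayed, 176 were weaker, 188 stronger and 0 reversed. Without 1 library 191 of 595 fold changes of named genes moved by over 1.5 times. All other totals stayed within 1.5 times, but the genes lower in bone marrow-derived cells went from 992 to 1731 at day 3 and from 1034 to 1880 at day 6 in a fit on only the groups compared. The smallest library held 5839316 counts, which limits genes of few counts.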

Other observations

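No test in this part was chosen after seeing the result.

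Some gene groups have not been described above. In iPSC-derived cells at day 12 against day 0, microglia transcription factor genes rose 8 of 14 with 1 fall (9 and 1 adjusted over the list alone), the MADS-box gene Mef2c by 1.71 and Runx1 by 1.83, with Bhlhe40 lower (-1.62). MHC class II genes were split, 4 of 10 higher and 4 lower, H2-DMa up by 1.66 and H2-Eb1 down (-5.09). Chemokine and chemokine receptor genes rose 10 of 25 with 5 falls (11 and 5 adjusted over the list alone), disease-associated microglia genes 9 of 24 with 5 falls (11 and 6 adjusted over the list alone), and purinergic receptor genes 5 of 13 with 3 falls. Neural progenitor genes rose 5 of 10 with 1 fall (6 and 1 adjusted over the list alone), Fabp7 by 3.75 with Vim lower (-2.90).

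In bone marrow-derived cells at day 12 against day 0, MHC class II genes rose 1 of 10 with 4 falls (2 and 4 adjusted over the list alone), and MHC class I genes rose 6 of 13 with 1 fall. LXR targets rose 10 of 14 with 1 fall, and immediate early genes 8 of 19 with 1 fall (8 and 2 adjusted over the list alone). Only 4 of 14 pluripotency genes and 2 of 14 lymphocyte genes had enough counts to be tested. Of these, 0 changed in either source (1 lymphocyte gene lower in bone marrow-derived cells when adjusted over the list alone). The pluripotency medians were 2.28 log2 units in iPSC-derived and 2.35 in bone marrow-derived cells. With genes at 0 counts set to their bound the latter was 0.7. Spp1 held 9.295% of the counts of iPSC-derived day 12 replicate 2, the largest share of any gene in any library.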
